A study of Mus musculus with 6 samples.

How the data were processed

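Brain RNA of 6 adult male mice was extracted with a column kit and made into Illumina TruSeq RNA libraries, per the labels' protocols. The submitters' processing notes name the mouse genome build GRCm38 and DESeq2, and the aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The deposited table has 43346 gene symbols, of which 20593 had counts in at least 1 library. It holds 1 column of raw counts per mouse, which the authors deposited without normalization, since the values are whole numbers with a different total in each library. Beside them, per the file headers, stand the results of the authors' DESeq2 comparison, with a mean normalized count and a log2 fold change with its standard error. The authors' test score, which is the log2 fold change divided by its standard error, and the p-value and adjusted p-value from it were made by DESeq2, per the file headers. The authors' log2 fold changes are wild type over deficient and smaller in size than ratios of the counts. The mean normalized count recomputed from the count columns matched the authors' deposited value to within 4.37e-10 in every row.

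Mice were assigned to genotypes by their titles and genotype labels, with 3 mice in each. The labels call the wild-type mice littermates of the deficient ones but name no litter, batch or day. The mouse numbers were not used as pairs. Totals were 22485616, 24531408 and 20170254 counts for deficient mice 1, 2 and 3, and 22853547, 18542590 and 23871215 for wild-type mice 1, 2 and 3. Mitochondrial transcripts made up 3.03% to 3.46% of the counts. A chi-square statistic of the counts over genes was 4.11 to 8.34 per degree of freedom in every pair of libraries, so no library was a duplicate of another.

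Counts were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the default expression filter, the robust quasi-likelihood fit and a two-sided F test. The p-values were adjusted by Benjamini and Hochberg over all 15030 genes tested, with a threshold of 0.05. Fold changes are deficient over wild type on the log2 scale, and their SE is the size of the fold change divided by the square root of F. CPM values use TMM-scaled library sizes. A gene at 0 in 1 group was given a lower bound against a floor of 3 counts over that group. Floors cover counting error only.

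Before the data were examined, 52 lists of genes were written down, with 901 different genes. Of these genes 894 had a row under the same symbol and 5 under an older one. Lists with at least 5 measured members (50) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the lists. Camera with a correlation estimated per list and fry were run beside it. Members were also adjusted over the list alone.

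The named genes were also fixed in advance. They are Kdm6a, Kdm6b and Uty, up to 10 genes with the smallest p in each direction past 5% FDR, filled up to 5 where fewer passed, and up to 4 members by smallest p of each list that passed, held a called gene or covered H3K27 methylation, immediate early genes, serotonin, neurons or glia. The last is the X chromosome neighbour of Kdm6a with the smallest p. A few genes that this rule takes are not reported here, and all counts of genes include them. Positions come from GENCODE release M21 on GRCm38, which placed 98.9% of the tested genes. A near-identical copy is a transcript of another gene at least 95% identical over at least 200 bases. Values of genes with such a copy are uncertain, because the handling of reads that match several places is not given in the sources used here. Among the named genes these include Gm6166, Scd1, Hba-a1, Lyz2, Cycs, Maoa and Ndufb11. Those that overlap genes on the opposite strand, whose reads cannot be told apart without the strand setting, include Myo5b, Kdm6b, Padi2, Brinp3, Junb, Zic1, Zic4, Grm4, Cbln1, Kcnq3, Cacna1h, Homer2, Shank1, Shank3, Rps14, Rpl30, Ndufb5, Ndufb11, Rbbp4, Nefm, Cux2, Dlx1, Cnp and Olig1. Among the deposited rows, 27 have a 5-digit number for a symbol and hold 0.350% of the counts. They stayed in the library totals and in the gene-wise test and were not named.

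The edgeR code was first run on simulated counts with the means, spread and library sizes of this comparison (14903 genes). It called 32% of genes changed 1.25-fold, 73.5% of those changed 1.5-fold, 83.7% of those changed 2-fold and 98% of those changed 4-fold, with 18 false calls among 170. In 20 simulated data sets with no change it made a median of 2 calls (0 to 6), and camera called 0 of 50 lists. The simulated genes vary independently of each other.

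Alternatives fixed in advance were RLE size factors, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, the mouse number as a block, each mouse left out, a prior count of 0.5, a threshold of 0.10, and both other list tests. A correction for transcript length and GC content by splines, and a fit without genes that have a near-identical copy, were added after seeing the data.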

Results

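Brain RNA was sequenced from 6 adult male C57BL/6 mice, 3 of them Kdm6a deficient and 3 wild-type littermates. The deficient mice came from crosses of females carrying a loxP-flanked Kdm6a with males carrying Thy1-Cre, a transgene that expresses Cre recombinase mainly in neurons. Kdm6a, also called Utx, is an X-linked histone demethylase that removes methyl groups from lysine 27 of histone H3. The libraries held 18542590 to 24531408 counts, and 15030 genes had enough counts to be tested. Levels are given as CPM, the counts scaled to a common library size. The comparison asked which transcripts of the brain differ when Kdm6a is deficient.

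Kdm6a itself was lower in the deficient mice, and its transcript was still present in all 3 of them. Its level was 24.3 ± 1.68 CPM (SD, n = 3) in the deficient mice and 34.6 ± 0.370 CPM (SD, n = 3) in the wild-type mice, a log2 fold change of -0.51 (SE 0.07, edgeR adjusted p = 0.00780) or 70.1% of the wild-type level. The raw counts were 500, 621 and 515 in deficient mice 1, 2 and 3, and 777, 647 and 821 in wild-type mice 1, 2 and 3. The gene lies on chromosome X at 18162575 to 18279936 (GRCm38, plus strand), and the counts cover the whole gene, not the loxP-flanked part alone. Kdm6b, the autosomal demethylase of the same family, had a log2 fold change of -0.07 (SE 0.07, edgeR adjusted p = 0.938). Uty, the Y-linked relative of Kdm6a, had a log2 fold change of 0.13 (SE 0.07, edgeR adjusted p = 0.885) and stood at 21.8 ± 0.804 against 19.96 ± 0.508 CPM (SD, n = 3 each). Without wild-type mouse 2, the Kdm6a log2 fold change was -0.51 with an edgeR adjusted p of 0.05001.

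Apart from Kdm6a, 4 genes were lower and 2 were higher in the deficient brains at a false discovery rate (FDR) of 5%. Crocc, which encodes rootletin, a structural protein of the ciliary rootlet, was lower at a log2 fold change of -0.58 (SE 0.07, edgeR adjusted p = 0.00780), with 43.6 ± 2.96 CPM against 65.3 ± 6.17 CPM (SD, n = 3 each). Otof, which encodes otoferlin, a calcium sensor of vesicle fusion best known from inner hair cells, was lower at -0.56 (SE 0.08, edgeR adjusted p = 0.0108). Myo5b, an unconventional myosin that moves recycling endosomes, was lower at -0.40 (SE 0.06, edgeR adjusted p = 0.0173). Scd1, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, was lower at -0.29 (SE 0.04, edgeR adjusted p = 0.0281) from a high level of 406.2 ± 9.30 CPM in wild-type mice (SD, n = 3).

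Gm6166 was higher and was counted only in the deficient mice. This processed pseudogene had 226, 244 and 177 counts in the deficient mice and 0 in each wild-type library, at least 207.5-fold higher against a floor of 3 counts over the wild-type group (edgeR adjusted p = 4.58e-08). Its sequence is 98.3% identical to Fabp5, a fatty acid-binding protein gene, so reads of either can be counted for the other and its value is uncertain.

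**Figure D1:**
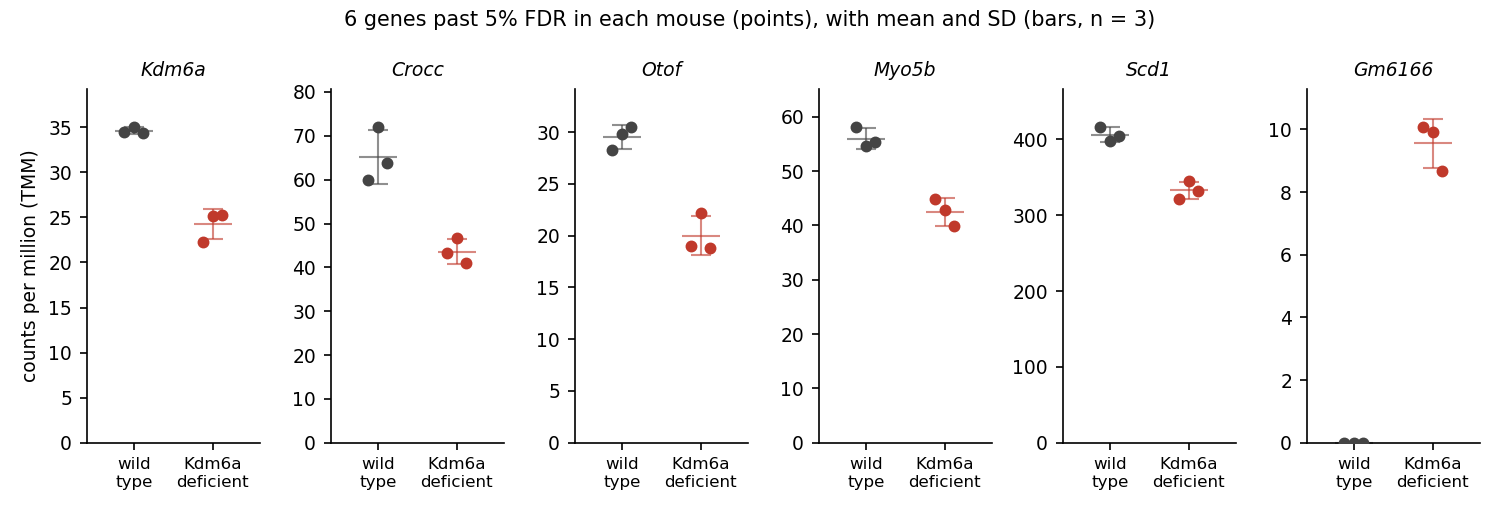
CPM (vertical axes, each from 0) of 6 genes past 5% FDR, with 1 point per mouse and bars for the mean and SD of the 3 mice of each genotype. The deficient mice lie below all wild-type mice for Kdm6a, Crocc, Otof, Myo5b and Scd1, and above them for Gm6166.

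The 7 calls were 2 higher and 5 lower of 15030 genes. In simulated counts the same test made 18 false calls among 170, and 0 to 6 calls where nothing changed. The 5% FDR is therefore nominal. A split of the 6 mice other than the genotype gave 34 calls. Gm6166 was past 5% FDR in each of the 6 fits that left out 1 mouse, and so was Crocc, whose log2 fold change was -0.51 (SE 0.09, adjusted p = 0.232) with a correction for transcript length and GC content. Otof was not past it without wild-type mouse 2 (edgeR adjusted p = 0.0557). Myo5b was not past it without deficient mouse 2 (0.111) or wild-type mouse 1 (0.158) or 2 (0.0557), nor with the length and GC correction (0.0514) or limma-voom (0.0603). Scd1, whose transcript is 95.5% identical to that of Scd2, passed only in the fit without wild-type mouse 3 among these 6, with adjusted p of 0.0632 to 0.268 in the others, and did not pass with limma-voom (0.0603). The number of calls was 12 without deficient mouse 1, 15 without deficient mouse 3, 3 without wild-type mouse 2 and 17 without wild-type mouse 3. It was 25 with no filter on low counts and 20 with DESeq2, which shared 7 and 6 of the 7 calls.

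Next in rank among genes with higher values in deficient brains were 3 that did not pass 5% FDR. Ccl28, a chemokine of mucosal tissues, had a log2 fold change of 0.87 (SE 0.15, edgeR adjusted p = 0.0881), with 5.33 ± 0.364 CPM against 2.92 ± 0.493 CPM (SD, n = 3 each). Padi2, an enzyme that converts arginine to citrulline in proteins and is abundant in oligodendrocytes, had a log2 fold change of 0.45 (SE 0.08, edgeR adjusted p = 0.0869). Brinp3, a gene expressed in neurons, had a log2 fold change of 0.30 (SE 0.05, edgeR adjusted p = 0.111). Padi2 had an adjusted p of 0.00307 and Ccl28 of 0.00531 with no filter on low counts, and both also passed with DESeq2. Padi2 also passed without wild-type mouse 3 (edgeR adjusted p = 0.0297), and Brinp3 with no filter on low counts (0.0204).

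Genes with small p-values were concentrated on the distal part of chromosome 4. Crocc (141016637 to 141060550) and Padi2 (140906344 to 140952586) lie within 1 Mb there (GRCm38). The segment from 125 to 145 Mb was chosen from the data. It had the smallest binomial p of all 20 Mb windows, taken every 5 Mb, with at least 50 tested genes. Of its 265 tested genes, 22 had an unadjusted edgeR p under 0.01 against 3.83 at the genome-wide rate. Of these 22, 9 were higher and 13 lower in the deficient mice. By binomial p, the fullest window of that size on another chromosome, 55 to 75 Mb of chromosome 14, had 8 such genes against 2.33. Splits of the mice other than the genotype also filled windows, on other chromosomes, with a -log10 binomial p of up to 14.0 against 10.1 here. Both Paqr7, a membrane progestin receptor gene, and Nbl1, a secreted antagonist of bone morphogenetic proteins, lie in the segment and were chosen after their values were seen. Their log2 fold changes were -0.27 (SE 0.05, edgeR adjusted p = 0.111) and 0.24 (SE 0.05, edgeR adjusted p = 0.191). Of the other genes described, Otof lies on chromosome 5 (30367062 to 30461932), Myo5b lies on chromosome 18 (74440936 to 74771493), Scd1 lies on chromosome 19 (44394455 to 44407879) and Gm6166 lies on chromosome 9 (57483963 to 57484371).

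**Figure D2:**
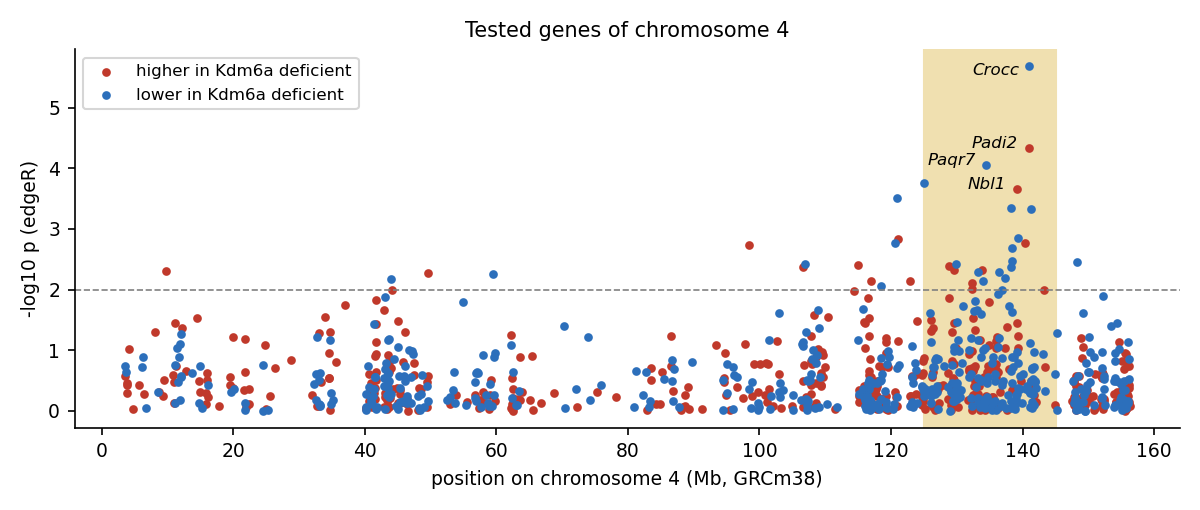
Unadjusted edgeR p of the tested genes of chromosome 4 on a -log10 scale (vertical axis) against their start position in Mb (horizontal axis), with genes higher in deficient mice in red and lower in blue. In the shaded segment from 125 to 145 Mb, 21 of the 22 genes with p under 0.01 (the dashed line) are drawn.

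Immediate early genes, which neurons switch on within minutes of activity, were lower as a group in the deficient brains by camera with its preset correlation. Of 32 measured members 27 had negative log2 fold changes, with a median of -0.17 (camera adjusted p = 5.14e-05, and p = 0.187, adjusted p = 0.900 with an estimated correlation). None passed 5% FDR over all genes tested, and 3 did adjusted over the list alone. Those were the transcription factor genes Fos at -0.72 (SE 0.12), Junb at -0.41 (SE 0.10) and Npas4 at -1.33 (SE 0.28), with edgeR adjusted p over the list alone of 0.00324, 0.0252 and 0.0357. Egr2 was next at -0.94 (SE 0.30) with 3.37 ± 0.383 CPM against 6.49 ± 2.48 CPM (SD, n = 3 each). Over all genes, Fos passed with no filter on low counts (edgeR adjusted p = 0.0324) and without deficient mouse 3 (0.0436), and Npas4 and Egr2 without wild-type mouse 3 (0.0173 and 0.0102). DESeq2 gave Fos, Junb and Npas4 an adjusted p of 7.33e-05, 0.0488 and 1.9e-06. The group's mean log2 CPM, relative to the wild-type mean, was -0.16, -0.26 and -0.23 in deficient mice 1, 2 and 3, and 0.20, -0.02 and -0.17 in wild-type mice 1, 2 and 3. The list was not past 5% FDR without wild-type mouse 1 (camera adjusted p = 0.154, median -0.06).

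Genes of the respiratory chain and of the ribosome were higher as groups by small amounts, by camera with its preset correlation. Of 38 nuclear-encoded oxidative phosphorylation genes 37 had positive log2 fold changes, with a median of 0.07 (camera adjusted p = 1.4e-05, and p = 0.256, adjusted p = 0.900 with an estimated correlation), and none passed 5% FDR singly. The group's mean log2 CPM relative to the wild-type mean was 0.10, 0.05 and 0.05 in deficient mice 1, 2 and 3, and -0.06, -0.00 and 0.06 in wild-type mice 1, 2 and 3, so that wild-type mouse 3 lay above deficient mice 2 and 3. After correction for transcript length and GC content its camera adjusted p was 0.0425. Ndufs7, of complex I, stood at 0.15 (SE 0.05), Uqcrc1, of complex III, at 0.10 (SE 0.04), and Ndufb5 at 0.11 (SE 0.05). Cycs, cytochrome c, stood at 0.14 (SE 0.06) and shares 99.9% of its aligned sequence with a pseudogene. The 13 transcripts encoded by mitochondrial DNA had a median log2 fold change of -0.00 (camera adjusted p = 0.896), with a mean of 0.02. Of 35 ribosomal protein genes 29 had positive log2 fold changes (median 0.05, camera adjusted p = 0.0330, and p = 0.359, adjusted p = 0.900 with an estimated correlation), with Rps14 at 0.13 (SE 0.07). Their mean relative to wild type was 0.10, 0.01 and 0.02 in deficient mice 1, 2 and 3. In wild-type mice 1, 2 and 3 it was -0.02, -0.04 and 0.06, so wild-type mouse 3 again lay above deficient mice 2 and 3. Rpl34 at 0.68 (SE 0.26) and Rpl30 at -0.45 (SE 0.21) went opposite ways and varied between mice, with an edgeR adjusted p of 0.000741 for Rpl34 without deficient mouse 1 and of 0.0224 for Rpl30 without wild-type mouse 2. The ribosomal list was not past 5% FDR after that correction (camera adjusted p = 0.331), nor without deficient mouse 1, wild-type mouse 1 or wild-type mouse 2 (0.278 to 0.343). It was also lost without genes that have a near-identical copy (0.261) and with no filter on low counts (0.0628).

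Voltage-gated ion channel genes and genes of postsynaptic scaffolds and plasticity kinases were lower as groups by camera with its preset correlation. Of 30 channel genes 25 had negative log2 fold changes, with a median of -0.06 (camera adjusted p = 0.0222, and p = 0.186, adjusted p = 0.900 with an estimated correlation). Adjusted over the list alone, 2 passed 5% FDR, Kcnq3, a subunit of the neuronal M-type potassium channel, at -0.20 (SE 0.05) and Cacna1h, a T-type calcium channel, at -0.18 (SE 0.05), both with an edgeR adjusted p of 0.0293 over that list. Cacna1i stood at -0.16 (SE 0.06) and Kcnd2 at 0.13 (SE 0.05). Of 28 scaffold and kinase genes 22 had negative log2 fold changes (median -0.04, camera adjusted p = 0.0473, and p = 0.241, adjusted p = 0.900 with an estimated correlation), with Homer2 at -0.16 (SE 0.06), Shank3 at -0.10 (SE 0.05) and Shank1 at -0.11 (SE 0.06). The channel genes' mean log2 CPM relative to the wild-type mean was -0.073, -0.061 and -0.033 in deficient mice 1 to 3. In wild-type mice 1 to 3 it was 0.035, -0.0049 and -0.031. For scaffolds the means were -0.024, -0.034 and -0.068 in deficient mice 1 to 3. They were 0.024, 0.00896 and -0.032 in wild-type mice 1 to 3, so wild-type mouse 3 lay below deficient mouse 1. After correction for transcript length and GC content the camera adjusted p was 0.725 for channels and 0.801 for scaffolds. Leaving out deficient mouse 2, wild-type mouse 1 or wild-type mouse 2 also ended both calls (camera adjusted p of 0.0673 to 0.368), as did deficient mouse 1 for channels (0.0697) and deficient mouse 3 for scaffolds (0.374). The scaffold list was also lost with no filter on low counts (0.0796) and without genes that have a near-identical copy (0.07995).

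Cerebellum markers and blood cell markers were higher as groups by camera with its preset correlation. Of 15 cerebellum markers 12 had positive log2 fold changes, with a median of 0.14 (camera adjusted p = 0.0247, and p = 0.290, adjusted p = 0.900 with an estimated correlation). The transcription factor gene Zic1, at 0.25 (SE 0.06), and the glutamate receptor gene Grm4, at 0.22 (SE 0.06), passed adjusted over the list alone (edgeR adjusted p of 0.0205 each over that list), and Zic1 over all genes without deficient mouse 1 (0.0349). Cbln1 stood at 0.19 (SE 0.07) and Zic4 at 0.25 (SE 0.10). The group's mean log2 CPM relative to the wild-type mean was -0.04, 0.16 and 0.23 in deficient mice 1, 2 and 3, and -0.08, 0.06 and 0.02 in wild-type mice 1, 2 and 3. Markers of midbrain and hindbrain monoamine neurons, not past 5% FDR as a list (camera adjusted p = 0.827), stood at -0.26, 0.25 and 0.30 in the same deficient mice and at -0.08, 0.00 and 0.08 in the wild-type mice. Among them Tph2, which encodes the serotonin-making enzyme of neurons, had 4.02, 13.4 and 12.1 CPM in deficient and 5.99, 6.93 and 9.16 CPM in wild-type mice 1, 2 and 3 (log2 fold change 0.41, SE 0.52, edgeR adjusted p = 0.953). Of 11 blood cell markers 10 had positive log2 fold changes (median 0.31, camera adjusted p = 0.0330, and p = 0.0375, adjusted p = 0.900 with an estimated correlation). The alpha globin gene Hba-a1 stood at 0.47 (SE 0.10, edgeR adjusted p = 0.00477 adjusted over the list alone), passed over all genes with no filter on low counts (0.0324), and is 99.8% identical to Hba-a2. S100a9 and S100a8, of neutrophils, stood at 0.91 (SE 0.37) and 0.53 (SE 0.33) on 8 to 32 counts per library, and Lyz2 at 0.26 (SE 0.11).

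The cerebellum list was not past 5% FDR without deficient mouse 2 or 3 or wild-type mouse 1 or 3 (camera adjusted p of 0.0674 to 0.384). The blood list was not past it without deficient mouse 1 or 2 or wild-type mouse 3 (0.0617 to 0.154), nor without genes that have a near-identical copy (0.314), with no filter on low counts (0.125), with a filter at a mean of 1 CPM (0.139) or after correction for transcript length and GC content (0.116). With fry, a rotation test, each of the 7 lists had an adjusted p of 0.849. Their estimated correlation ran from -0.04 for blood cell markers to 0.53 for oxidative phosphorylation, against the preset 0.01. By camera with the preset correlation, 8 of the 10 ways to part the mice 3 against 3 gave at least 7 lists. These include the real one, and the most was 16, so the number of lists does not set the genotype apart.

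**Figure D3:**
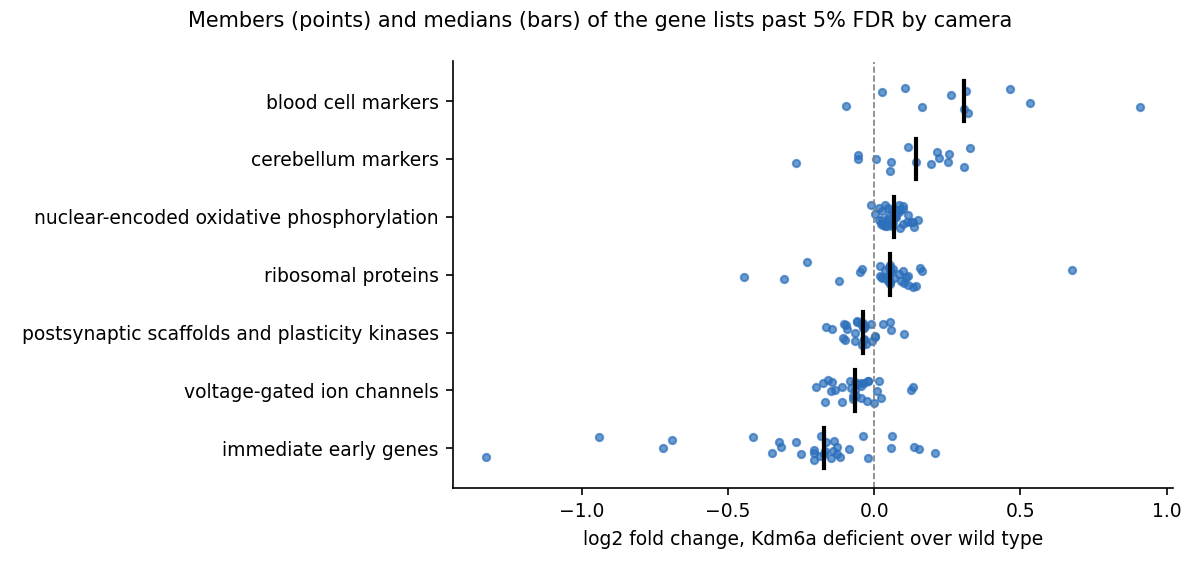
Log2 fold change, deficient over wild type (horizontal axis), of each measured member (points, spread vertically for visibility) of the 7 gene lists past 5% FDR by camera with its preset correlation. Bars mark the medians, from -0.17 for immediate early genes to 0.31 for blood cell markers.

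Genes that write, erase or read methylation of histone H3 lysine 27 showed no shared direction. Of 15 members Kdm6a alone passed 5% FDR, both over all genes and adjusted over the list alone, and 8 of the log2 fold changes were negative (median -0.02, camera adjusted p = 0.827). E130012A19Rik stood at -0.19 (SE 0.07, edgeR adjusted p = 0.729), and Rbbp4, a histone-binding subunit of Polycomb repressive complex 2, at 0.10 (SE 0.05, edgeR adjusted p = 0.850). Polycomb-silenced developmental regulators are genes that this histone mark keeps off in adult tissue. Of 43 listed, 30 were measured, with a median log2 fold change of 0.05 and a mean of -0.02 (camera adjusted p = 0.896). The test leaves out the unmeasured members, so it cannot speak for genes that stayed off. Of 29 Hox genes 4 were measured, too few for the list test. Each of the 4 had a positive log2 fold change (median 0.22), and none passed 5% FDR. Members of Polycomb repressive complex 1 had a median of 0.02 (camera adjusted p = 0.940, with a mean of -0.00 and a lower camera direction). A list of 14 COMPASS family methyltransferases and subunits of their complexes had a median of 0.03 (camera adjusted p = 0.618). Of 27 measured X chromosome neighbours of Kdm6a 17 had positive values (median 0.03, camera adjusted p = 0.296), and the one with the smallest p was Ndufb11 at 0.12 (SE 0.05, edgeR adjusted p = 0.771).

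No list of neuron or glia marker transcripts was past 5% FDR. Pan-neuronal markers had a median log2 fold change of -0.02 (camera adjusted p = 0.837), with Stmn2 at 0.12 (SE 0.04), Eno2 at -0.06 (SE 0.04), Nefm at -0.06 (SE 0.04) and Thy1, whose promoter drives the Cre transgene, at 0.05 (SE 0.04). Excitatory neuron markers had a median of -0.03 (camera adjusted p = 0.262), with Cux2 at -0.11 (SE 0.05), Camk2a at -0.10 (SE 0.06), Crym at -0.13 (SE 0.08) and Rorb at -0.10 (SE 0.07). Inhibitory neuron markers had a median of 0.03 (camera adjusted p = 0.912), with Lhx6 at -0.18 (SE 0.07), Calb2 at -0.13 (SE 0.06), Dlx2 at 0.27 (SE 0.14) and Dlx1 at 0.46 (SE 0.29). Astrocyte markers had a median of 0.01 (camera adjusted p = 0.827), with Slc1a3 at 0.05 (SE 0.04) and Atp1b2 at -0.04 (SE 0.04). Oligodendrocyte markers had a median of -0.02 (camera adjusted p = 0.555), with Myrf at -0.11 (SE 0.05), Cldn11 at -0.09 (SE 0.05) and Cnp at -0.09 (SE 0.05). Their precursors' markers had a median of -0.00 (camera adjusted p = 0.986), with Olig1 at -0.08 (SE 0.05). Microglia markers had a median of -0.02 (camera adjusted p = 0.618), with C1qb at -0.27 (SE 0.09), C1qc at -0.15 (SE 0.09) and Siglech at 0.15 (SE 0.10). C1qb and C1qc lie between 125 and 145 Mb of chromosome 4. None of these markers passed 5% FDR.

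Serotonin receptor and metabolism genes were not past 5% FDR as a group (18 measured, median 0.06, camera adjusted p = 0.555). The receptor gene Htr1d, which also lies between 125 and 145 Mb of chromosome 4, stood at -0.46 (SE 0.14, edgeR adjusted p = 0.563) with 3.44 ± 0.369 CPM against 4.73 ± 0.173 CPM (SD, n = 3 each). Maoa, which breaks serotonin down, stood at 0.11 (SE 0.05), Htr1a at 0.15 (SE 0.07) and Htr2c at 0.10 (SE 0.07). None passed 5% FDR.

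Library composition differed between single mice. Wild-type mouse 3 held 23860 counts of growth hormone, Gh (998.1 CPM against 0.433 to 5.88 CPM in the other 5), and 8942 of prolactin, Prl, transcripts of the anterior pituitary. Its choroid plexus transcript Ttr, at 1129 CPM, was the highest of the 6, whose lowest was 596.2 CPM in deficient mouse 1. The first principal component of log2 CPM held 24.4% of the variance and set wild-type mouse 3 apart, at 21.6. The second held 23.0% and put deficient mouse 1 at -17.7 and wild-type mouse 2 at 19.9. The third held 19.6% and set deficient mouse 3 apart, at 21.5. None of the first 3 components separated the genotypes. Spearman correlations between libraries, over genes, were 0.996 to 0.997 within and between genotypes. The female-specific transcript Xist had 0 counts in each library.

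In the authors' deposited table of their own DESeq2 comparison, 18 genes had an adjusted p under 0.05, of which 16 were higher in wild-type mice. The authors' deposited table gave Kdm6a a log2 fold change, wild type over deficient, of 0.33 (adjusted p = 3.26e-05) and Crocc 0.39 (adjusted p = 3.96e-08). Scd1, Otof and Myo5b were also past 5% in the authors' deposited table, so that 5 of the 7 genes called by edgeR were in both, while Gm6166 has no adjusted p in it. Fos at 0.33 (adjusted p = 8.08e-05) and Junb at 0.24 (adjusted p = 0.0446) were higher in wild-type mice in the authors' deposited table, and Padi2 (-0.25) and Ccl28 (-0.20) higher in deficient mice. Over 11837 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the edgeR fit had a Spearman correlation of 0.980, with both taken as deficient over wild type.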

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

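The length and GC correction and the fit without near-identical copies were chosen after seeing the data. The Kdm6a log2 fold change stayed between -0.55 and -0.46 in 14 alternatives and passed 5% FDR in 13 of them, the exception being the fit without wild-type mouse 2 (-0.51, edgeR adjusted p = 0.05001). The edgeR test as first set called 7 genes, 2 higher and 5 lower. With no filter on low counts it was 25 (9 higher, 16 lower), with a filter at a mean of 1 CPM 1 was higher, with DESeq2 it was 20 (17 lower), with limma-voom 3 were lower (adjusted p = 0.0603 for Myo5b and Scd1), with the length and GC correction 3 were lower (0.0514 for Myo5b), without near-identical copies 1 was higher, and at a threshold of 0.10, 4 were higher. Leaving out 1 mouse gave 3 to 17 genes, 1 to 6 higher and 2 to 11 lower. The mouse number as a replicate block gave 15 genes (5 higher, 10 lower), with all 7 of those calls among them, and Fos and Junb also passed (edgeR adjusted p = 0.0228 each), while the postsynaptic scaffold list did not (camera adjusted p = 0.0715). Whether the mouse numbers pair the samples is not known. Deviations of same-numbered mice correlated weakly, at -0.000634, 0.0810 and 0.0480. Mouse 1 did not correlate best with its own number while 2 and 3 did. With 3 mice per genotype these values cannot exclude a pairing.

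Of the lists, 7 passed by camera with the preset correlation, 4 higher and 3 lower. It was 4 with no filter (2 higher), 4 with the length and GC correction (1 lower) and 4 without near-identical copies (2 higher), and 5 were lower with DESeq2 and with limma-voom. It was 0 with an estimated correlation and 0 with fry, in both directions, where the smallest adjusted p among the 7 lists was 0.900 and 0.849. Leaving out 1 mouse gave 4 to 8 lists, 3 to 4 higher and 1 to 5 lower. Oxidative phosphorylation passed in 15 of 17 alternatives and immediate early genes in 14. Cerebellum markers passed in 11 of 17, ion channels in 10, ribosomal proteins in 9, blood cell markers in 8 and postsynaptic scaffolds in 7. Every passing fit kept the preset correlation of 0.01, so these counts do not test that setting. The estimated correlation was 0.53 for oxidative phosphorylation and 0.35 for immediate early genes. The length and GC correction removes trends with those properties by construction, and the cause of the other shifts was not tested.

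A few named genes with folds near 0 changed sign when 1 mouse was left out. Over the 6 fits without 1 mouse the log2 fold change ranged from -0.010 (without deficient mouse 1) to 0.075 for Pdgfra, from -0.017 (without deficient mouse 2) to 0.12 for Sox9, from -0.079 to 0.0067 (without deficient mouse 3) for Aldh1l1, from -0.12 to 0.017 (without wild-type mouse 1) for Kdm6b, and from -0.037 (without deficient mouse 3 or wild-type mouse 3) to 0.11 for Vcan. Over all named genes and alternatives, 979 values kept their direction and side of the threshold, 15 were no longer past it and 19 newly passed. Depth limits genes with few counts, such as S100a8 with 8 to 22 per library.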

Other observations

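Among neuropeptide and transmitter receptor genes, a few passed 5% FDR adjusted over their list alone and none over all genes, and these examples were chosen after their values were seen. Adjusted over the neuropeptide list alone, Adcyap1, which encodes the peptide PACAP, had a log2 fold change of 0.39 (SE 0.08, edgeR adjusted p = 0.00560 over the list, 0.191 over all genes). Pdyn, which encodes the opioid precursor prodynorphin, stood at -0.28 (SE 0.07, edgeR adjusted p = 0.0112 over the list, 0.356 over all genes). Among glutamate receptor genes Grin2c at 0.19 (SE 0.05), Grin3a at 0.17 (SE 0.05) and the cerebellum marker Grm4 passed adjusted over the list alone (edgeR adjusted p = 0.0438 each, and 0.539, 0.565 and 0.502 over all genes), and among GABA receptor genes Gabra5 at 0.21 (SE 0.06, edgeR adjusted p = 0.0471 over the list, 0.530 over all genes). The lists themselves did not pass, with camera adjusted p of 0.618 for neuropeptides, 0.326 for glutamate receptors and 0.278 for GABA receptors. Choroid plexus markers had negative log2 fold changes in 13 of 14 members (median -0.18, camera adjusted p = 0.102), with a group mean of -0.51 in deficient mouse 1 relative to the wild-type mean and -0.05 and 0.12 in the other deficient mice.

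Except for the splits of the list count and of the immediate early genes and the search for near-identical copies in the chromosome 4 segment, the tests that follow were chosen after the result was seen. The 6 mice can be parted 3 against 3 in only 10 ways, too few for a share under 0.05. Of these, 2 gave at least as many genes past 5% FDR, namely the real one with 7 and another with 34, and the real one had 881 genes with an unadjusted p under 0.05, fewer than 3 of the other 9 (983, 1004 and 1165). The split with 34 set deficient mice 1 and 2 with wild-type mouse 2 against the rest, which points to a structure of the samples other than the genotype. The first principal component, made from the same counts and so not separate evidence, divides the mice in the same way. Deficient mice 1 and 2 and wild-type mouse 2 lay at -8.37, -13.2 and -8.18 on it. Deficient mouse 3 and wild-type mice 1 and 3 lay at 1.49, 6.63 and 21.6. For the gene lists 8 of the 10 ways gave at least 7 lists, the most being 16.

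The chromosome 4 segment at 125 to 145 Mb, which holds Crocc and Padi2, went both ways. Reads shared with near-identical copies are argued against. Such a copy exists for 9.09% of the segment's genes with p under 0.01, against 10% of all tested genes. A gained or lost copy of the whole segment is also argued against. Its 265 genes had a median log2 fold change of -0.022 (95% bootstrap interval -0.04 to -0.00, with genes and not mice resampled). A median over all of these genes cannot exclude a gained or lost copy of a small part of the segment. In 6 of the 9 other splits a window on some other chromosome was filled beyond the highest of 100 shuffles of gene positions, with a -log10 binomial p of up to 14.0 against 10.1 for the real split. One candidate explanation is therefore DNA segments that differ between these mice, whether carried along with an engineered allele or segregating by chance, although neighbouring genes that are regulated together would also fill windows. Whether the segment follows from Kdm6a deficiency was not tested, and no sequence variants were used here.

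Gm6166 may owe its counts to reads of Fabp5. Fabp5 had a log2 fold change of -0.26 (SE 0.06, edgeR adjusted p = 0.356), and the sum of both had one of 0.028 (SE 0.06, edgeR adjusted p = 0.976), at 49.8 to 55.6 CPM in deficient and 48.5 to 55.8 CPM in wild-type mice. Allelic differences between mice that do not follow the genotype are also a candidate, since 9 other genes switched between at most 3 and at least 30 counts along other splits of the mice, 2 of them pituitary genes found in wild-type mouse 3. Among the 9, Eno1b, which has the near-identical copy Eno1, had 422, 457, 365 and 386 counts in deficient mice 1 to 3 and wild-type mouse 1 but 0 and 1 in wild-type mice 2 and 3. With Gm6166 there were 10 switching genes, of which 8 could be searched for a near-identical copy and 5 had one. Shared reads could therefore also give such switches, which do not tell the 2 candidates apart. An allele of either gene that tracks the genotype cannot be separated here from an effect of Kdm6a, which stays untested.

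The lower immediate early genes could reflect neuronal activity or handling before collection, which no label records, as well as Kdm6a itself. A smaller share of excitatory neurons is argued against as the whole cause. Their markers had a median log2 fold change of -0.027 (95% bootstrap interval -0.08 to -0.00) against -0.17 for the list. The markers' mean relative to wild type was 0.04, -0.03 and -0.11 in deficient mice 1 to 3, against -0.16, -0.26 and -0.23 for the list. In wild-type mice 1 to 3 the markers stood at 0.05, 0.00 and -0.05. The bootstrap intervals resample genes and not mice, so they do not measure the spread between mice. A smaller share of hippocampus stays open. Of 12 dentate gyrus and hippocampus markers 9 had negative log2 fold changes, with a median of -0.109 (95% bootstrap interval over genes -0.19 to 0.03, camera adjusted p = 0.262). However, their mean relative to wild type was -0.06, 0.01 and -0.27 in deficient mice 1 to 3, and the immediate early genes were lowest in deficient mouse 2. A single wild-type library also stays open, since the median of the list was -0.057 without wild-type mouse 1 and -0.14 to -0.29 without any other mouse. The splits are too few to judge chance, with a median of 0.17 in size for the real one and 0.25 for the highest other, and 2 of 10 at least as large as the real one, so the genotype, the share of hippocampus and the single library cannot be told apart.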
